A study of Homo sapiens and Mus musculus with 5 samples.

How the data were processed

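Single-cell RNA sequencing of unsorted cells from collagenase-digested tumors was examined in 5 libraries: 1 of mouse breast tumors, 2 of human breast tumors and 2 of human pancreatic tumors. Per the labels' protocols, the suspensions of individual samples were marked with hashtag antibodies (an antibody carrying a DNA tag) before they were loaded for 10x Genomics 3′ v3 chemistry. The deposited matrices hold unique molecular identifier (UMI) counts of genes and of hashtags per cell barcode. Per the file headers they were made with Cell Ranger 4.0.0, and per the submitters' processing notes reads were aligned to mm10 or GRCh38 and analysed with Seurat 3.1.1. The tables list 31053 mouse and 33538 human genes. Gene positions were taken from GENCODE annotation on GRCh38. No table of cell types or of hashtag-to-donor assignments was used here, so cells were named anew.

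The mouse breast library held 12266 barcodes with 26066870 gene UMIs. The human breast libraries held 5617 and 5897 barcodes with 15881695 and 18406434 gene UMIs, and the pancreatic libraries 1704 and 1857 barcodes with 12091917 and 13203958 gene UMIs. Barcodes with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs were kept. The limit on mitochondrial UMIs removed 362 barcodes of the mouse library, 843 and 797 of the human breast and 330 and 354 of the pancreatic libraries. Doublets were ranked by Scrublet and the highest scores removed at an assumed rate of 0.8% per 1000 barcodes. This removed 1137 barcodes in the mouse library, 201 and 224 in human breast, and 14 and 23 in the pancreatic libraries, where Scrublet's own thresholds called 0, 99, 104, 3 and 6 in the same order. After both steps 10358 mouse, 4572 and 4875 human breast and 1359 and 1478 pancreatic cells remained, with median UMIs per cell of 1496, 1584.5, 1715, 6889 and 7312.5. The pancreatic cells thus carried about 4 times the UMIs of the human breast cells. Free RNA was not subtracted. A gene is named as one that free RNA could account for when its level in a class lay far below that in another named class. The level was taken in the tissue where the class had more of it. Cells left unnamed were not counted as a source, so a gene without that remark is not cleared of free RNA.

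Each of the 3 groups was clustered on its own with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.0). A cluster was named after the best-scoring cell class when at least 3 of that class's fixed markers passed. A marker passed when its mean was higher, by a log2 fold of at least 1, than in the lower quartile of clusters, when it was found in at least 10% of the cluster's cells, and when it reached at least 20% of the level of the highest cluster. A cluster was left unnamed when another class reached 60% of its markers, when more markers of another class stood among its 10 leading genes, or when it had few UMIs and none of its own markers among them. The names are by markers alone and are written with -like. The scoring rule had 3 versions, changed after the clusters were seen and before any comparison of tissues; the earlier ones were kept as alternatives. Classes were compared between tissues only where each of the 4 human libraries had at least 20 cells. This left fibroblast-like, mural-like, macrophage-like and T/NK-like cells. Endothelial-like cells, with 7 and 11 pancreatic cells, and epithelial-like cells, with no named pancreatic cluster, were not compared between tissues. The mural-like class holds pericytes and smooth muscle cells together.

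For each class, gene UMIs were summed per library and the 2 pancreatic libraries compared with the 2 human breast libraries in edgeR 4.0.16 under R 4.3.3 (low-count filter, TMM scaling, robust quasi-likelihood test, Benjamini-Hochberg adjustment over the genes tested, threshold 0.05). Log2 values are pancreatic over breast; levels are CPM, counts scaled to a common total, with SD over the 2 libraries of a tissue, and errors of log2 values are SE. A difference of tissue effects between fibroblast-like and macrophage-like cells was tested as an interaction with a library effect. Altogether 32 fixed gene lists were tested in fibroblast-like cells with camera (limma 3.58.1; preset correlation 0.01) and, beside it, with an estimated correlation and with fry. In the other classes members of the lists were counted as risen, fallen or not called. Where a gene had 0 UMIs in a tissue, a lower bound of the fold was taken against a floor of 3 counts; with 1 to 3 UMIs a ratio with a 95% counting interval was used. Shares of cells carry exact Clopper-Pearson intervals. Intervals and floors cover counting error only.

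Across species, the level of each gene in fibroblast-like cells was divided by that in all other kept cells of the same library, unnamed clusters included. The alternative with the other classes weighted equally used named classes only. Log2 ratios were compared over genes with a symbol shared between mouse and human by Spearman's rho (genes of at least 1 CPM, pseudocount 1). Co-variation of a list within fibroblast-like cells was the mean pairwise Pearson correlation over cells, set against 10000 random lists matched on expression among the 100 nearest genes. As an alternative each cell was thinned to 1000 UMIs, which left out 33 mouse, 112 and 125 human breast and 3 and 4 pancreatic fibroblast-like cells below that number. Fibroblast-like cells were also subclustered within each group (resolution 0.5). Subclusters were paired when each was the other's best match by correlation of centred mean profiles. Genes used had a mean log level above 0.2 in a subcluster of both groups.

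Genes to be named were fixed by rule. They are the 8 with the largest fold in each direction among those called, with a mean log2 CPM of at least 5 and the same direction in all 4 pairs of libraries, and up to 4 members per fixed list with the smallest adjusted p. Members of the lists examined across species are also named. Sex-linked genes, immunoglobulin and T-cell receptor segments, haemoglobins, mitochondrial and ribosomal protein genes and clone names were left out. HLA genes whose presence follows a donor's haplotype are not reported, and some other genes that the rule selects are not reported here. The lists and their tests, the settings and their alternatives were written before the data were examined, except for those named next. Chosen afterwards were the version of marker scoring and its alternatives, and the lists counted in mural-like, macrophage-like and T/NK-like cells (before their tests). The sums thinned to equal totals and the comparisons with breast cells split by hashtag were also chosen afterwards. So was the choice of interaction genes to name (the 10 largest with opposite calls in both classes, a mean log2 CPM of at least 5 and no share of free RNA that could account for them).

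Both breast libraries carried the same 3 hashtags in nearly the same proportions, and both pancreatic libraries carried 1 hashtag. The libraries of a tissue were therefore not taken for separate donors, although the tags alone do not settle this, and p values between 2 and 2 libraries measure spread between libraries, not between people. As an alternative, breast cells were assigned to hashtags by a mixture model (posterior at least 0.9; 4658 of 9447 cells) or by a 2-fold margin, and the hashtag sums of at least 15 cells were compared with 1 pancreatic sum. With 1 pancreatic sum the spread in these comparisons came from the breast sums alone, so calls kept or lost there reflect no pancreatic spread. The mixture model gave 3 breast sums in each class. The margin gave 3 in fibroblast-like cells and 2 in the others, where hashtag 9 had 2 mural-like, 9 macrophage-like and 12 T/NK-like cells. Among cells assigned by both rules, 98.6% of those that the mixture model gave to hashtag 8 got the same tag by margin, 100.0% for hashtag 10 and 43.6% for hashtag 9. The hashtag 9 sums are thus the least certain. With a single pancreatic hashtag and 1 mouse library, differences between tissues or species cannot be told from differences between donors, animals or preparations.

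The tests were also tested on simulated data at the depth and size of each class. Of genes changed 4-fold, 78.7% were recovered in fibroblast-like, 73.8% in mural-like, 92.1% in macrophage-like and 90.1% in T/NK-like cells, and 2-fold changes in 29.1%, 35.1%, 58.3% and 49.0%. In the fibroblast-like run 2 of 11476 unchanged genes were called. A planted list was called at 1.29e-08 and 0 of 100 unchanged lists were called. The simulated genes were drawn independently, so this does not show how often camera calls unchanged lists of correlated genes. Other settings tried were stricter and looser cell filters, no removal of doublets, resolutions 0.5 and 2.0, equal cell numbers, DESeq2 1.42.0, another scaling, leaving out each library, and a term for the replicate number.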

Results

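Cancer-associated fibroblasts were compared between tumors of the breast and of the pancreas and between human and mouse, the question named in the title of the series. The libraries hold all cells of the digested tumors, so the fibroblasts were set beside mural cells, macrophages and T/NK cells of the same tumors. In the comparisons of tissues n = 2 libraries per tissue throughout; both libraries of a tissue carried the same hashtags and were not taken for separate donors, and the mouse tumors gave 1 library.

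Fibroblast-like cells made up a far larger share of the pancreatic libraries than of the breast libraries. They were 580 of 1359 kept cells (42.7%, 95% interval 40.0 to 45.4) and 662 of 1478 (44.8%, 42.2 to 47.4) in the pancreatic libraries. They were 336 of 4572 (7.35%, 6.61 to 8.14) and 380 of 4875 (7.79%, 7.06 to 8.58) in human breast, and 1040 of 10358 (10.0%, 9.47 to 10.6) in mouse breast. Mural-like cells, the pericytes and smooth muscle cells around vessels, averaged 4.91 ± 0.441% in pancreatic and 1.45 ± 0.249% in breast libraries (SD, n = 2). T/NK-like cells averaged 28.0 ± 0.517% against 14.4 ± 2.50%. Macrophage-like cells went the other way, with 6.78 ± 0.302% in pancreatic and 27.4 ± 2.21% in breast libraries. A pancreatic cluster led by S100A8 (2.43% and 2.50% of cells) and one led by CD1C and FCER1A (2.36% and 2.17%), closest to macrophages but left unnamed, are not in that share. The pancreatic and breast libraries did not overlap in any of these classes, but an exact permutation test of 2 against 2 libraries cannot go below p = 0.333 (two-sided), so no share was called different.

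Epithelial-like cells were 41.6% and 40.9% of the human breast libraries and no pancreatic cluster was named epithelial-like. Endothelial-like cells were 5.64% and 5.42% in breast and 0.515% and 0.744% in pancreas. B-like cells were 28.5% and plasma-like cells 15.5% of the mouse library, where no cluster was named mural-like or endothelial-like. The pancreatic classes were sequenced more deeply. Fibroblast-like cells had a median of 11965.5 and 11835 UMIs in pancreas and of 1294 and 1299 in breast, and T/NK-like cells 1947 and 1975 against 624 and 615. The T/NK share moved most with the minimum of UMIs per cell, since a minimum of 1000 left a mean of 1.39% in breast and 24.7% in pancreas. Clusters left unnamed held 11.8% and 12.3% of the pancreatic cells, none of the human breast cells and 7.41% of the mouse cells. Among those of the pancreas, a keratin-high cluster with fibroblast markers held 3.83% and 3.45%, a NOV and GAP43 cluster with fibroblast and Schwann cell markers 1.69% and 2.23%, and a fibroblast cluster of low UMI count 1.47% and 1.96%.

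**Figure D1:**
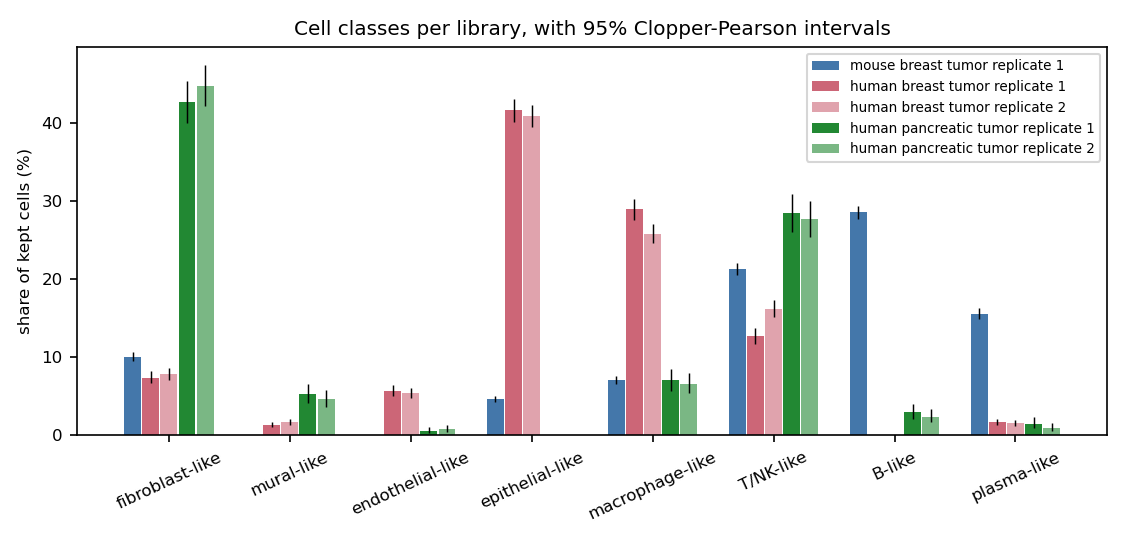
Share of kept cells (%) in each class, by library; bars are shares and lines their 95% Clopper-Pearson intervals. Fibroblast-like cells stood at 42.7% and 44.8% in the pancreatic libraries and at 7.35% and 7.79% in the human breast libraries.

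Fibroblast-like cells of the breast tumors had more RNA of MMP11, POSTN and FN1, and those of the pancreatic tumors more of C7 and TCF21. MMP11, a stromelysin of tumor stroma (ENSG00000099953, GRCh38 chromosome 22, 23768226 to 23784316), stood at 2244 ± 42.7 CPM in breast and 26.2 ± 1.54 in pancreas (log2 -6.42 ± 0.09, adjusted p = 3.36e-45). POSTN, a matricellular protein (ENSG00000133110, chromosome 13, 37562583 to 37598844), stood at 4446 ± 147 and 254 ± 3.98 CPM (log2 -4.13 ± 0.07, adjusted p = 1.03e-41). FN1, which encodes fibronectin (ENSG00000115414, chromosome 2, 215360440 to 215436172), stood at 8099 ± 65.4 and 903 ± 101 CPM (log2 -3.16 ± 0.07). In the other direction C7, a terminal complement component (ENSG00000112936, chromosome 5, 40909252 to 40982939), stood at 30.2 ± 4.29 CPM in breast and 2012 ± 22.8 in pancreas (log2 6.07 ± 0.12, adjusted p = 7.45e-38). TCF21, a transcription factor of visceral mesenchyme (ENSG00000118526, chromosome 6, 133889138 to 133895553), had 0 UMIs in the breast sums and 107 ± 9.17 CPM in pancreas, at least 42.7-fold higher (adjusted p = 6.29e-18).

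The other genes of largest fold in fibroblast-like cells were of mixed function. Higher in pancreatic tumors were DPEP1, a dipeptidase, with 1 UMI in breast (ratio 147, interval 26.4 to 5830), the bradykinin receptor BDKRB1 (48.0, 13.3 to 397), SCRG1 (47.1, 16.1 to 229), and G0S2, a brake on lipolysis (45.4, 12.5 to 376). The nuclear receptor NR4A3 rose too (log2 5.10 ± 0.21). The chemokine CXCL3 also rose, but free RNA could account for it. Lower in pancreatic tumors were the proteoglycan SDC1 (log2 -3.51), the matricellular TNC (-3.42), the adhesion molecule VCAM1 (-2.97), TGFBI (-2.95) and C12orf75 (-2.77). Of 12221 genes tested, 3912 were called, 2103 higher and 1809 lower in pancreatic tumors. With breast cells split by hashtag into 3 sums and set against 1 pancreatic sum, 437 of 5033 genes were called, and 428 of these were among the 3912.

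Myofibroblast genes fell on balance in pancreatic tumors, but not as a block. Of 12 myofibroblastic genes 2 rose, 9 fell and 1 was not called, with 2 and 9 adjusted over the list alone; with breast cells split by hashtag 1 rose and 4 fell. CTHRC1, a collagen-associated secreted protein, fell with MMP11 and POSTN (log2 -1.44 ± 0.06, adjusted p = 3.65e-24), and ACTA2, smooth muscle actin, fell by 0.42 on the log2 scale. CNN1, the contractile protein calponin, rose from 23.2 ± 1.41 to 275 ± 15.6 CPM (log2 3.56 ± 0.17, adjusted p = 7.44e-23), THY1 rose (log2 0.36), and TAGLN did not change (log2 0.06, adjusted p = 0.475). The list was called down by camera (adjusted p = 0.00924, median log2 -0.53). Its adjusted p was 0.397 with an estimated correlation, as it was for each of the 11 lists that camera called. No list had a lower value in that setting, and basement membrane genes, which camera did not call, shared it. With 2 libraries per tissue an estimated correlation could hardly call any list, so 0.397 speaks neither for nor against a call. Fry, which tests whether genes move on balance one way, gave the myofibroblastic list an adjusted p of 0.00565.

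Genes of the inflammatory fibroblast phenotype rose. Of 12, 8 rose, 0 fell and 4 were not called (8 and 0 adjusted over the list alone; 5 and 0 with breast cells split by hashtag). Free RNA could account for 2 of the 12. HAS1, a hyaluronan synthase, rose from 3.02 ± 4.27 to 96.8 ± 6.59 CPM (log2 4.85 ± 0.36, adjusted p = 3.82e-15). The neutrophil chemokine CXCL2 (3.82 ± 0.30), the prostaglandin synthase PTGS2 (4.01 ± 0.43), the cytokine LIF (3.15), the monocyte chemokine CCL2 (1.57 ± 0.10) and CXCL12 (0.50) rose as well. CXCL14 was not called (log2 -1.18, adjusted p = 0.102). Some of the risen genes were lower in pancreatic fibroblast-like cells than in all other kept cells, unnamed clusters with fibroblast markers included. The log2 ratios in replicates 1 and 2 were -1.566 and -1.917 for HAS1 and -1.085 and -1.135 for CXCL2. They were -0.995 and -1.051 for PTGS2 and -0.545 and -0.276 for CCL2. LIF (1.096 and 0.277) and CXCL12 (3.174 and 2.165) were higher than in those cells. The list was called up by camera (adjusted p = 0.00375, and 0.397 with an estimated correlation); fry gave an adjusted p of 0.0568 for movement one way and of 0.0111 for change in either direction.

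Matrix genes fell selectively. Of 15 genes of fibrillar collagen and cross-linking 2 rose, 9 fell and 4 were not called (2 and 10 adjusted over the list alone; 0 and 5 with breast cells split by hashtag). The collagens of activated stroma COL11A1 (log2 -1.81 ± 0.07), COL10A1 (-2.08 ± 0.08), COL12A1 (-1.53 ± 0.07) and COL5A2 (-1.01 ± 0.06) fell, as did the cross-linking enzyme LOXL2 (-2.56). The bulk collagens COL3A1 (0.50) and COL1A1 (0.44) rose and COL1A2 was not called (0.09, adjusted p = 0.229). Of 14 matrix proteases and inhibitors 2 rose, 9 fell and 3 were not called (2 and 11 adjusted over the list alone; 1 and 2 with the hashtag split). The plasminogen activator PLAU (log2 -2.34 ± 0.10), the metalloproteases ADAM12 (-2.10 ± 0.11) and MMP14 (-1.30), and FAP, a fibroblast activation marker (-0.95), fell, whereas MMP19 (2.79 ± 0.15) and MMP2 (0.87) rose. Camera called both lists down, with adjusted p = 0.00480 for collagens and 0.00144 for proteases, and with 0.397 for each with an estimated correlation. With the hashtag split the call was lost for proteases (adjusted p = 0.114) and not for collagens (0.0110). Of 10 basement membrane genes 1 rose, 4 fell and 5 were not called (1 and 5 adjusted over the list alone; camera adjusted p = 0.1). The laminin chain LAMA2 rose (log2 1.02), and COL18A1 (-0.63) and NID2 (-0.98) fell.

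Signalling programs separated further. Of 14 immediate early and heat shock genes 12 rose and 2 fell (12 and 2 adjusted over the list alone; 8 and 0 with the hashtag split). The AP-1 subunits FOSB (log2 3.33 ± 0.09), JUND (2.72 ± 0.07) and JUNB (2.42 ± 0.08) and the RNA-binding ZFP36 (2.53 ± 0.08) were among the risen, and the heat shock genes HSPA1A (-0.39) and HSPA1B (-0.60) were the fallen ones. Camera called the list up (adjusted p = 3.02e-05, median log2 1.75; 0.397 with an estimated correlation; fry 0.0184). Of 11 interferon-response genes 1 rose and 10 fell (1 and 10 adjusted over the list alone; 0 and 8 with the hashtag split). ISG15, an interferon-induced ubiquitin-like protein, fell from 1062 ± 142 to 206 ± 9.95 CPM (log2 -2.37 ± 0.08, adjusted p = 6.62e-28). IFI27 (-2.15 ± 0.07) and IFI6 (-1.88 ± 0.08) fell with it, whereas BST2 rose (0.64). Camera called the list down (adjusted p = 1.22e-05, median log2 -1.88; 0.397 with an estimated correlation; fry 0.0184). Of 12 TGF-beta genes 4 rose, 5 fell and 3 were not called (5 and 5 adjusted over the list alone; camera adjusted p = 0.985). The co-repressor SKIL (log2 1.35) and the ligand TGFB3 (1.21) rose. LRRC15, a marker of TGF-beta-driven fibroblasts, fell (-2.47 ± 0.17) with TGFB1 (-0.95). Of 16 genes of focal adhesion and mechanotransduction 3 rose, 7 fell and 6 were not called (3 and 8 adjusted over the list alone; camera adjusted p = 0.284). The YAP targets CYR61 (log2 2.71 ± 0.07) and CTGF (1.03 ± 0.06) rose and the collagen receptor ITGA11 (-2.68 ± 0.14) fell.

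Complement and tissue-identity genes also differed. C3, the central complement component (ENSG00000125730, chromosome 19, 6677704 to 6730562), rose from 365 ± 45.9 to 1946 ± 63.5 CPM (log2 2.43 ± 0.08, adjusted p = 1.04e-28). The proteases C1R (1.06) and C1S (0.74) rose while CD55, which protects cells from complement, fell (-0.93). Of 9 complement genes tested 4 rose, 1 fell and 4 were not called (4 and 1 adjusted over the list alone; camera adjusted p = 0.1; 1 and 0 with the hashtag split). Of 22 positional transcription factors 9 rose, 7 fell and 6 were not called (10 and 8 adjusted over the list alone; camera adjusted p = 0.985). HOXC8 (log2 -3.93 ± 0.38), HOXC6 (-2.71 ± 0.29), TBX15 (-5.60) and TBX5 (-4.36) fell, and GATA6 (1.88), WT1 (2.11) and HOXA5 (1.93) rose. With the hashtag split HOXC6 was called and HOXC8 was not (adjusted p = 0.430). Of 13 genes of steady-state fibroblasts 4 rose, 3 fell and 6 were not called (4 and 3 adjusted over the list alone; camera adjusted p = 0.477). C7, DPT (log2 1.10) and CFD (0.67) rose and GSN (-0.41) fell. MFAP5 fell by 0.54 on the log2 scale but rose by 0.34 without removal of doublets. The growth factor VEGFA rose (log2 2.70 ± 0.14), although of 11 genes of hypoxia and glycolysis 1 rose and 4 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.262). Of 7 proliferation genes 6 fell (6 adjusted over the list alone), among them TOP2A (log2 -4.35 ± 0.47; 31 and 17 UMIs). The list was called down by camera (adjusted p = 0.000311; 0.397 with an estimated correlation), but neither the list (adjusted p = 0.338) nor any of its genes was called with the hashtag split.

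Antigen presentation genes fell in fibroblast-like cells, in part within reach of free RNA. Of 10 class I genes 1 rose and 9 fell (1 and 9 adjusted over the list alone), and none was called with the hashtag split. B2M, the invariant light chain, stood at log2 -0.92 ± 0.06 and the proteasome subunit PSMB9 at -1.35 ± 0.14, while HLA-E rose (0.25). Of 9 class II genes 0 rose and 8 fell (9 adjusted over the list alone), but RNA from other cells could account for each of the 9. HLA-DRA fell from 105 ± 2.67 to 11.3 ± 1.04 CPM (log2 -3.22 ± 0.19) and CD74 stood at log2 -2.90 ± 0.17. Camera called class I (adjusted p = 0.00148) and class II (5.43e-06) down, with 0.397 for each with an estimated correlation. Genes that fibroblasts should lack moved in the same direction. T-cell cytotoxic genes were called down by camera (adjusted p = 0.000117, and 0.397 with an estimated correlation). Immune cells in the same droplet were not excluded as a source of the class II and T-cell RNA in breast. The breast fibroblast-like cells held a subcluster of 35 cells led by CCL5, CD3D and GZMA and another of 8 led by CD74 and HLA-DRA. No pancreatic subcluster was led by such genes. Of 7 mammary luminal genes 5 fell and 0 rose (7 and 0 adjusted over the list alone; camera adjusted p = 1.22e-05, and 0.397 with an estimated correlation). MUCL1, a breast secretory product, stood at 259 ± 66.5 CPM in breast and 1.09 ± 0.183 in pancreas. Of 8 immunoglobulin and immune genes 3 fell (3 adjusted over the list alone; camera adjusted p = 0.0934), and of 7 epithelial keratin genes 2 fell (2 adjusted over the list alone; camera adjusted p = 0.233).

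Smaller lists in fibroblast-like cells moved little or both ways. Of 6 lipid-handling genes 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.401, median log2 0.46 and mean -0.31, test direction up). The alcohol dehydrogenase ADH1B rose (log2 1.05 ± 0.14) and the lipase LPL fell (-4.01 ± 0.59). Of 8 steroid receptors and targets 4 rose and 1 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.694), with the clock gene PER1 rising (log2 2.06 ± 0.18). Of 7 stellate and retinoid genes, a program of pancreatic stellate cells, 1 rose and 1 fell, the latter PDGFRB (log2 -0.64 ± 0.09; 1 and 2 adjusted over the list alone; camera adjusted p = 0.821).

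**Figure D2:**
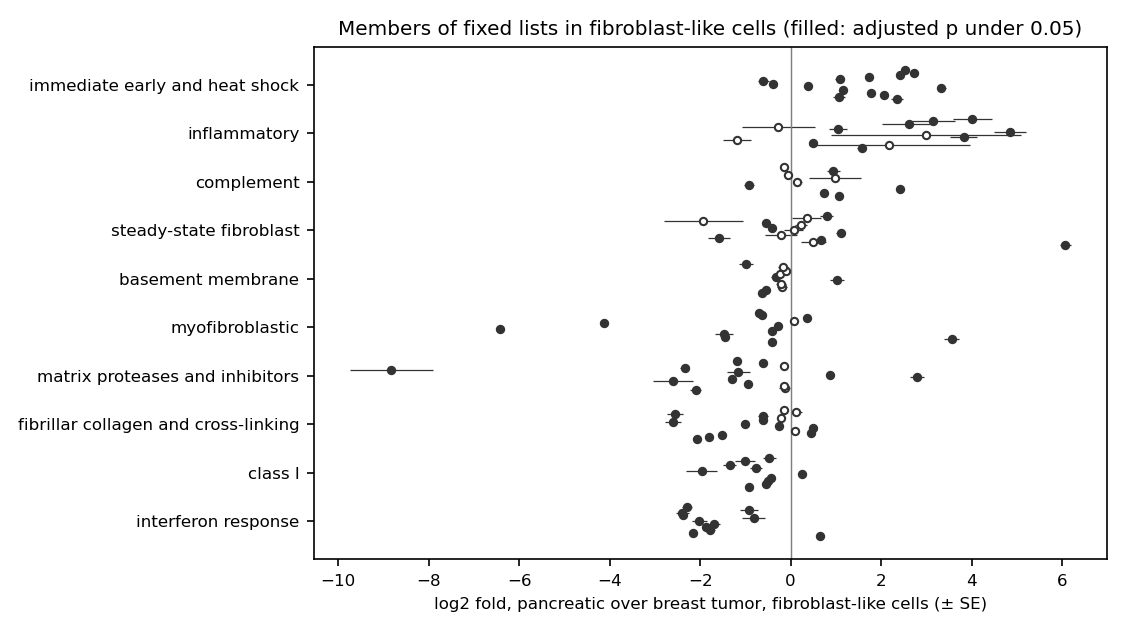
Log2 fold of pancreatic over breast tumors for members of 10 fixed lists in fibroblast-like cells; points are genes, lines SE, filled points have an adjusted p under 0.05. Immediate early genes lay mostly to the right (12 of 14 rose) and interferon-response genes to the left (10 of 11 fell).

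Mural-like cells of pancreatic tumors had more contractile and less collagen RNA. MYH11, smooth muscle myosin (ENSG00000133392, chromosome 16, 15703172 to 15857033), rose from 435 ± 41.7 to 1468 ± 32.9 CPM (log2 1.77 ± 0.16, adjusted p = 1.04e-08). LMOD1 (2.48 ± 0.39), TAGLN (0.75 ± 0.10) and MYL9 (0.69 ± 0.11), which serve actin filaments, rose with it. Of 8 contractile genes 6 rose, 0 fell and 2 were not called (6 and 1 adjusted over the list alone; 3 and 0 with the hashtag split). COL4A1, a basement membrane collagen (ENSG00000187498, chromosome 13, 110148963 to 110307233), fell from 3140 ± 138 to 1041 ± 31.0 CPM (log2 -1.60 ± 0.11, adjusted p = 1.75e-10). Of 9 basement membrane genes 8 fell and HSPG2 (log2 1.77) rose (1 and 8 adjusted over the list alone; 0 and 4 with the hashtag split). Of 11 fibrillar collagen genes 0 rose, 7 fell and 4 were not called (0 and 9 adjusted over the list alone). COL1A1 (log2 -2.43 ± 0.13), COL3A1 (-2.21 ± 0.12), COL5A2 (-2.40 ± 0.19) and COL1A2 (-2.07 ± 0.12) were among the fallen. The breast class was 1 cluster of 137 cells led by the pericyte gene RGS5. The pancreatic class was 2 clusters, 77 cells led by RGS5 and STEAP4 and 62 by MYH11 and ACTG2. The rise of contractile genes was therefore not separated from a change in the mix of pericytes and smooth muscle cells. The breast cluster also had 2 fibroblast markers raised, and genes of fibroblasts such as POSTN and THY1 fell with the collagens, so RNA of fibroblasts in the breast class was not excluded.

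Of 4686 genes tested in mural-like cells 453 were called, 261 higher and 192 lower in pancreatic tumors; with breast cells split by hashtag 106 were called. The genes of largest fold on the higher side all had 0 UMIs in breast. They were the immediate early factor EGR3 (at least 4.95-fold), the amino acid transporter SLC7A5 (at least 4.76-fold), GPAT2 (at least 4.26-fold) and the collagen chain COL4A5 (at least 3.82-fold). Next came KLF4 and CASP9 (at least 3.57-fold each), PTGER1 (at least 3.39-fold) and NPDC1 (at least 3.07-fold). Of these COL4A5, KLF4, CASP9, PTGER1 and NPDC1 were not called by DESeq2 (adjusted p = 0.0720, 0.0868, 0.0888, 0.105 and 0.15). On the lower side stood ADAM12 (log2 -4.47 ± 0.58), the hyaluronan-binding TNFAIP6 (-4.07 ± 0.52), SPON2 (-3.59), MXRA5 (-3.50), POSTN (-3.22 ± 0.26), OLFML3 (-2.96) and the laminin chain LAMB1 (-2.84); free RNA could account for HLA-DRA (-4.21). Without one of the 4 libraries the adjusted p reached 0.0995 for TNFAIP6 and 0.2 for MXRA5.

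Lists counted in fibroblast-like cells were also counted in mural-like cells; differences between these classes were not tested. Of 14 immediate early and heat shock genes 10 rose and 0 fell (10 and 1 adjusted over the list alone), with ZFP36 at log2 2.78 ± 0.19 and JUND at 2.30 ± 0.15. Of 11 interferon-response genes 5 fell and 6 were not called (9 fell adjusted over the list alone; 1 with the hashtag split), IFIT3 at -2.37 ± 0.42 and IFI27 at -1.30 ± 0.22. Of 10 class I genes 3 fell (5 adjusted over the list alone), and of 11 myofibroblastic genes 3 rose and 3 fell (3 and 3 adjusted over the list alone), THY1 among the fallen (log2 -1.94 ± 0.20). Of 10 matrix proteases and inhibitors 2 rose and 4 fell (2 and 5 adjusted over the list alone), the inhibitor TIMP3 rising (log2 1.07 ± 0.17) and TIMP1 falling (-1.58 ± 0.16). Of 4 hypoxia genes VEGFA (log2 2.20 ± 0.56) and LDHA (0.69 ± 0.18) rose (2 adjusted over the list alone), and neither was called by DESeq2 (adjusted p = 0.264 and 0.214). Of 5 steroid receptors and targets FKBP5 fell (log2 -1.19; 2 rose and 1 fell adjusted over the list alone), and of 2 positional factors none was called (1 rose over the list alone).

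Macrophage-like cells of pancreatic tumors had more RNA of most genes of resident macrophages, and those of breast tumors more of interferon-response genes and of most genes of lipid-laden macrophages. MRC1, the mannose receptor and one of the markers used to name the class, rose from 14.9 ± 5.83 to 821 ± 28.8 CPM (log2 5.77 ± 0.15, adjusted p = 1.17e-32). The lectin CLEC10A rose from 17.7 ± 10.8 to 400.3 ± 15.6 CPM (4.5 ± 0.19, adjusted p = 1.47e-16). F13A1, a coagulation factor of resident macrophages (ENSG00000124491, chromosome 6, 6144085 to 6321013), rose from 21.6 ± 0.0745 to 253 ± 9.40 CPM (3.54 ± 0.16, adjusted p = 2.25e-23). CXCL10, an interferon-induced chemokine (ENSG00000169245, chromosome 4, 76021117 to 76023497), fell from 684 ± 45.1 to 10.7 ± 2.37 CPM (-5.99 ± 0.20, adjusted p = 9.21e-29). APOE, the lipid carrier (ENSG00000130203, chromosome 19, 44905754 to 44909393), fell from 7096 ± 325 to 769 ± 90.2 CPM (-3.21 ± 0.09, adjusted p = 6.33e-31). The breast class held 6 clusters, among them 1220 cells led by GPR34 and complement C1Q genes, 682 by CCL3 and IL1B, 314 by CD1E and FCER1A and 184 by CXCL11, IFIT2 and CXCL10. The pancreatic class was 1 cluster of 192 cells led by C1QC, CD163, FOLR2 and F13A1. The breast class thus includes a cluster led by CD1E and FCER1A, while the pancreatic cluster led by CD1C and FCER1A was left unnamed, so the classes were not drawn alike.

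The other genes of largest fold in macrophage-like cells were, on the higher side, the chitinase CHIT1 (log2 7.09 ± 0.67, 1.33 to 196 CPM), THBS1 (5.45 ± 0.65), the hyaluronan receptor LYVE1 (5.33 ± 0.73) and the growth factor EREG (4.35 ± 0.15). Of these THBS1, LYVE1 and EREG, as well as MRC1, were not called with breast cells split by hashtag (adjusted p = 0.163, 0.0716, 0.194 and 0.0881), and LYVE1 not by DESeq2 (0.0779). On the lower side stood IFI27 (-5.25 ± 0.19), OLFML3 (-4.85 ± 0.29) and the chemokine CXCL11 (-4.85 ± 0.36). Free RNA could account for the mammary products that also fell, TFF3 (at least 27.1-fold lower), SCGB1D2 (at least 18.9-fold lower), SCGB2A2 (1 UMI in pancreas; ratio 130, interval 23.2 to 5160) and MUCL1 (log2 -6.10). Of 9158 genes tested 2725 were called, 1542 higher and 1183 lower in pancreatic tumors.

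By list, 8 of 11 resident macrophage genes rose and 2 fell (8 and 2 adjusted over the list alone; 6 and 1 with the hashtag split). FOLR2, a folate receptor, stood at log2 2.14 ± 0.15 and C1QB at -0.76 ± 0.09. Of 12 genes of lipid-laden and matrix-remodelling macrophages 3 rose and 7 fell (3 and 8 adjusted over the list alone), APOC1 (log2 -2.63 ± 0.13) and CD9 (-1.17 ± 0.11) falling and the protease CTSB (0.94 ± 0.09) rising. Of 12 inflammatory macrophage genes 6 rose and 2 fell (6 and 2 adjusted over the list alone). The chemokines CXCL2 (log2 2.70 ± 0.12) and CXCL8 (2.21 ± 0.11) and NLRP3 (0.90 ± 0.17) rose and TNF fell (-0.96). CXCL2 was not called with the hashtag split (adjusted p = 0.207). Of 9 class II genes 6 rose and 1 fell (6 and 1 adjusted over the list alone), HLA-DPB1 at log2 0.71 ± 0.08 and HLA-DRA at 0.44 ± 0.07. Of 10 class I genes 5 fell (6 adjusted over the list alone), B2M at -0.68 ± 0.08. All 11 interferon-response genes fell (11 adjusted over the list alone; 10 with the hashtag split), IFIT1 at log2 -4.10 ± 0.18 and ISG15 at -1.94 ± 0.10. All 14 immediate early and heat shock genes rose (14 adjusted over the list alone and with the hashtag split), JUND at 2.03 ± 0.09 and FOSB at 1.67 ± 0.10. Of 11 hypoxia genes 4 rose and 1 fell (5 and 2 adjusted over the list alone), VEGFA (log2 2.23 ± 0.12) and ADM (2.33 ± 0.23) among the risen. Of 4 complement genes C3 (-3.95 ± 0.13) and SERPING1 (-1.41 ± 0.22) fell and CD55 (2.50 ± 0.15) rose (1 and 3 adjusted over the list alone). Among 8 immune genes 4 rose and 1 fell (4 and 1 adjusted over the list alone), lysozyme LYZ at log2 2.47 ± 0.08. Of 6 lipid-handling genes 2 rose and 2 fell (2 and 2 adjusted over the list alone), the droplet protein PLIN2 at 1.37 ± 0.12. The 7 mammary genes all fell (7 adjusted over the list alone), and free RNA could account for each.

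T/NK-like cells of pancreatic tumors had more AP-1 and less interferon-induced RNA. JUN, an AP-1 subunit (ENSG00000177606, chromosome 1, 58780788 to 58784327), rose from 412 ± 35.4 to 4012 ± 115 CPM (log2 3.27 ± 0.08, adjusted p = 8.44e-53). ISG15 (ENSG00000187608, chromosome 1, 1001138 to 1014540) fell from 1291 ± 189 to 120.0 ± 16.5 CPM (log2 -3.43 ± 0.11, adjusted p = 1.06e-37). IFI27 (ENSG00000165949, chromosome 14, 94104836 to 94116698) fell from 306 ± 76.3 to 6.48 ± 7.11 CPM (-5.43 ± 0.29, adjusted p = 6.99e-26). GNLY, the granule protein granulysin, fell from 870.3 ± 27.1 to 203 ± 7.36 CPM (-2.10 ± 0.11, adjusted p = 3.72e-31). Other genes of largest fold were the heat shock gene HSPA6 (log2 4.77 ± 0.68), the semaphorin receptor PLXND1 (3.76 ± 0.41) and HIST1H2BG (3.24 ± 0.49). They included the phosphodiesterase PDE4D (3.22 ± 0.21) and SPRY1, an inhibitor of growth factor signalling (3.18 ± 0.31), all higher in pancreatic tumors. ANKRD30A, a mammary gene, had 0 UMIs in pancreatic T/NK-like cells (at least 49.9-fold lower). Free RNA could account for SOCS3 on the higher side and for SCGB2A2, TFF3, PIP, KRT19, MUCL1 and AIF1 on the lower side.

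Of 7047 genes tested in T/NK-like cells 1640 were called, 797 higher and 843 lower in pancreatic tumors; with breast cells split by hashtag 527 were higher and 376 lower. The make-up of the class differed, too. Of the breast clusters 701 cells were led by GNLY, 524 by KLRB1 and IL7R and 144 by TNFRSF18, TNFRSF4 and FOXP3, and of the pancreatic ones 520 by CD8B and CD8A, 222 by KLRB1 and CD40LG, 31 by GNLY and 22 by TNFRSF4, IL2RA and FOXP3. Changes of the lists were therefore not separated from changes in the mix of cells. Of 10 cytotoxic genes 4 rose and 5 fell (4 and 6 adjusted over the list alone). The chemokine CCL5 (log2 0.79 ± 0.07) and perforin PRF1 (1.05) rose and the granzyme GZMA (-0.79 ± 0.10) and IFNG (-0.85 ± 0.15) fell. IFNG was not called with the hashtag split (adjusted p = 0.407). Of 6 genes of regulatory T cells 0 rose and 5 fell (5 adjusted over the list alone; 2 with the hashtag split). The costimulatory receptors TNFRSF4 (log2 -1.82 ± 0.16) and TNFRSF18 (-1.50 ± 0.18) and the factor FOXP3 (-1.44 ± 0.35) were among them. FOXP3 was not called by DESeq2 (adjusted p = 0.122) or with the hashtag split (0.279). Of 6 genes of naive and memory cells 2 rose and 3 fell (3 and 3 adjusted over the list alone). LEF1 (log2 -2.62 ± 0.48) and CCR7 (-1.58 ± 0.29), which mark naive cells, fell and the cytokine receptor IL7R (0.43 ± 0.07) rose. Of 9 checkpoint genes HAVCR2 rose (log2 1.23) and the chemokine CXCL13 fell (-3.48; 1 and 1 adjusted over the list alone), neither of them by DESeq2 (adjusted p = 0.399 and 0.403). All 11 interferon-response genes fell (11 adjusted over the list alone and with the hashtag split). Of 14 immediate early and heat shock genes 11 rose and 0 fell (11 and 1 adjusted over the list alone; 10 and 0 with the hashtag split), DUSP1 at 2.30 ± 0.10. Of 10 class I genes 4 fell (5 adjusted over the list alone), PSMB9 at log2 -1.54 ± 0.11. The 7 mammary genes and 3 keratin genes all fell (7 and 3 adjusted over the list alone), and free RNA could account for each of them.

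**Figure D3:**
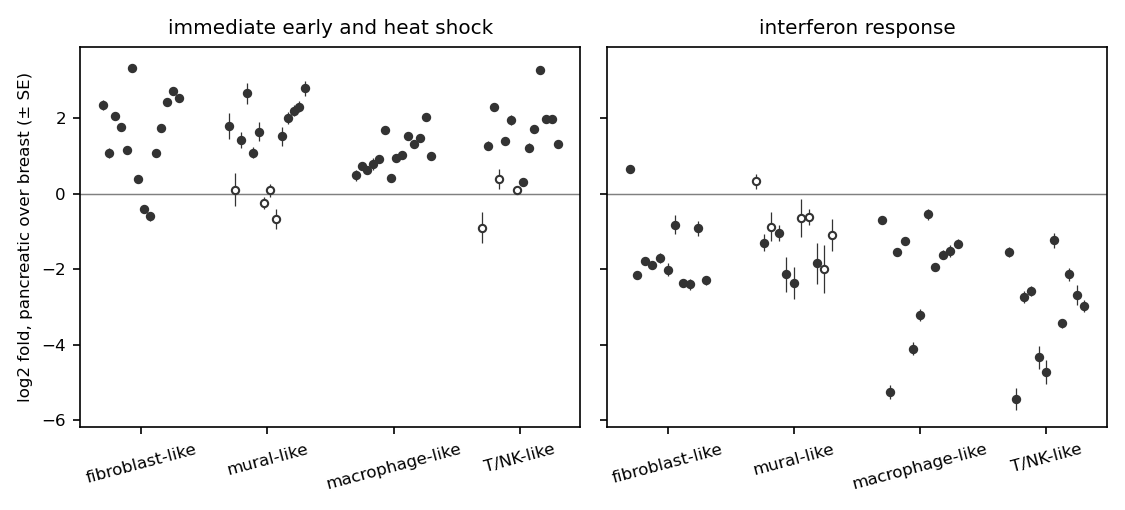
Log2 fold of pancreatic over breast tumors for immediate early and heat shock genes (left) and interferon-response genes (right) in 4 cell classes; points are genes in the same order in each class, lines SE, filled points have an adjusted p under 0.05. In macrophage-like cells all 14 genes of the left panel rose and all 11 of the right panel fell.

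The effect of tissue differed between fibroblast-like and macrophage-like cells for part of the genes. Of 11218 genes tested for interaction 1613 were called. Of 1161 genes called in both classes, 919 moved in the same direction, 704 of them with no interaction called, and 242 moved in opposite directions. Free RNA could account for the gene in one of the classes for 43 of the 242. C3 rose in fibroblast-like cells (log2 2.43) and fell in macrophage-like cells (-3.95), an interaction of 6.43 ± 0.15. MMP2, a gelatinase, likewise rose in fibroblast-like cells (0.87) and fell in macrophage-like cells (-3.76; interaction 4.70 ± 0.29, adjusted p = 1.22e-55). So did OLFML3 (1.52 and -4.85; interaction 6.45 ± 0.29, adjusted p = 4.23e-102), the factor NFATC2 (3.47 and -2.15; 5.68 ± 0.39, adjusted p = 1.78e-44) and PTGS2 (4.01 and -0.57; 4.65 ± 0.48, adjusted p = 3.22e-20). F13A1 fell in fibroblast-like cells (-6.45, to 6 UMIs) and rose in macrophage-like cells (3.54; interaction -9.90 ± 0.51, adjusted p = 9.36e-80). The same directions held for PTPRE, a phosphatase (-2.93 and 1.82; -4.69 ± 0.33, adjusted p = 9.22e-44), and TMEM158 (-1.57 and 3.62; -5.19 ± 0.63, adjusted p = 1.67e-14). The RNA-binding KHDRBS3 (interaction 4.71 ± 0.70) and the junction protein CLDN1 (4.69 ± 0.59) rest on few UMIs. KHDRBS3 was lower in pancreatic macrophage-like cells by a ratio of 4.32 (interval 1.37 to 21.9), and CLDN1 higher in pancreatic fibroblast-like cells by a ratio of 5.70 (1.92 to 27.9), each with 3 UMIs in the lower group.

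Across species, the level of a gene in fibroblast-like cells was set against that in all other kept cells of the library, unnamed clusters included. In pancreas these held the unnamed keratin-high, NOV and GAP43, and low-UMI clusters with fibroblast markers. Pancreatic ratios are thus taken in part against cells with fibroblast markers. Of 12 myofibroblastic genes 10 were above those cells in all 5 libraries and 2 were mixed; lists were not tested against each other. CTHRC1 stood at a log2 ratio of 7.95 in mouse, 5.39 and 5.60 in human breast and 3.63 and 3.14 in pancreas. INHBA, an activin subunit, stood at 3.25, 8.10, 7.84, 3.96 and 4.03 in the same order, and POSTN at 7.14, 8.45, 8.32, 0.60 and 0.31. Of 11 inflammatory genes 4 were above the other cells in all 5 libraries, 2 below in all and 5 mixed. CXCL12 (7.49, 3.14, 2.88, 3.17 and 2.17) and CXCL14 (6.48, 7.09, 7.85, 6.23 and 3.23) were among the shared ones. CCL2 (3.14, 3.20, 3.51, -0.55 and -0.28) was above in the breast libraries of both species only. Of 14 genes of steady-state fibroblasts 4 were above in all 5 and 10 mixed. DPT (8.84, 7.56, 7.77, 2.70 and 2.11) was shared, and MFAP5 (8.90, 7.16, 7.36, -0.09 and -0.76) was not. MFAP5 was, however, a leading gene of the unnamed pancreatic NOV and GAP43 cluster, which counts among the other cells. Both class II genes with a shared symbol, CD74 (-3.18, -3.42, -3.61, -7.38 and -7.59) and CIITA, were below the other cells in all 5 libraries.

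**Figure D4:**
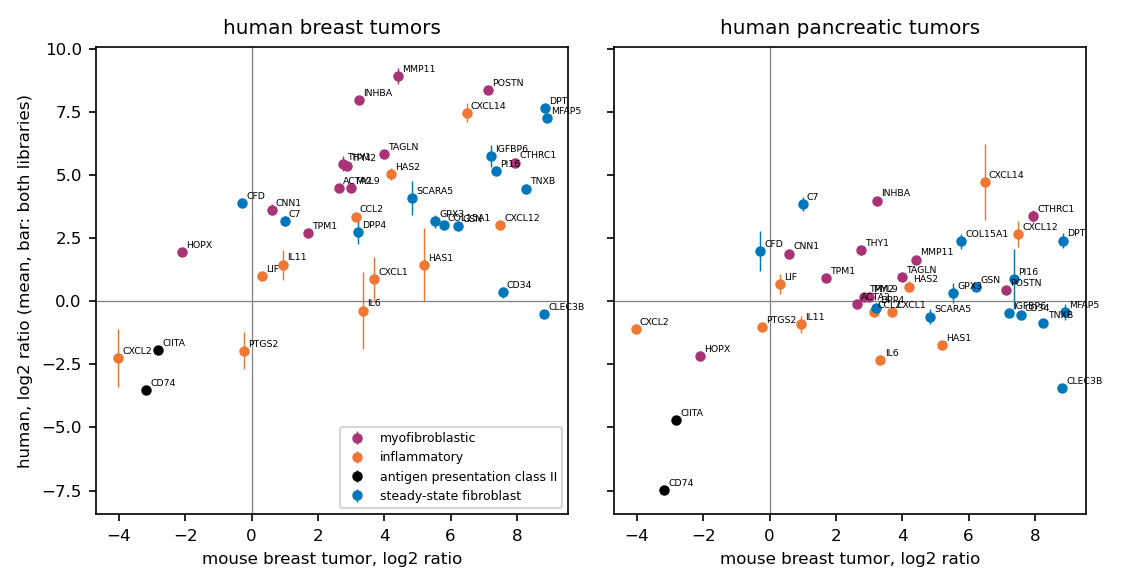
Log2 ratio of fibroblast-like cells to all other kept cells, unnamed ones included, for members of 4 lists. The x axis is the mouse breast library. The y axis is human breast (left) or pancreatic (right) libraries (mean of 2 libraries, bars reach to both). Myofibroblastic genes such as CTHRC1 lay above 0 on both axes in both panels.

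Over all genes, the order of closeness between the fibroblast profiles of the 3 groups depended on the choice and weights of the other cells. Spearman's rho across genes was 0.451 between mouse and human breast (0.444 and 0.459 for the 2 libraries) and 0.489 between mouse breast and human pancreas (0.492 and 0.486). It was 0.445 between human breast and human pancreas (0.434 to 0.456 over 4 pairs), among 10 pairs of libraries computed. With the other named classes weighted equally and unnamed cells left out, the values were 0.470, 0.501 and 0.593. The human tissues were then closest to each other. Within a tissue it was 0.816 in breast and 0.9 in pancreas. No mouse cluster was named endothelial-like or mural-like. An unnamed mouse cluster of 53 cells with markers of both is in the reference unless classes are weighted equally. Genes are not independent replicates. Of 16114 genes with a shared symbol 124 were at least 4-fold above the other cells in all 5 libraries. Of 169 that were so in the 4 human libraries 8 lay below the other cells in mouse, COL10A1 among them (-0.08 in mouse and 9.0, 8.74, 5.47 and 4.75 in human). A ratio of -0.08 is close to no difference, and a gene at the floor would have such a ratio. COL10A1 was thus not raised in mouse fibroblast-like cells, but it is not shown to be lower there than in the other cells. Of 1635 genes at least 4-fold above the other cells in the mouse library 111 lay below in all human libraries. Among them was CLEC3B, a plasminogen-binding matrix protein (8.83 in mouse and -0.64, -0.35, -3.47 and -3.44 in human). In human breast it lay at the floor, with 0 CPM in fibroblast-like cells and 0.556 and 0.276 in the others. In pancreas it was a leading gene of the unnamed NOV and GAP43 cluster with fibroblast markers, which counts among the other cells. A difference between species is therefore not shown for CLEC3B.

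Within fibroblast-like cells of one library, fibrillar collagen, myofibroblast and interferon genes varied together in every library. Fibrillar collagen genes had a mean pairwise r of 0.194 in mouse, 0.217 and 0.252 in human breast and 0.229 and 0.244 in pancreas, above all 10000 matched random lists each time. Myofibroblastic genes had 0.0946, 0.246, 0.243, 0.220 and 0.205, at or above the 99.97th percentile, and interferon-response genes 0.0970, 0.25, 0.295, 0.144 and 0.176, each at the 100th. Inflammatory genes varied together in mouse (0.0513) and pancreas (0.15 and 0.136), each at the 100th percentile, but not in human breast (0.0116 and 0.0175, percentiles 48.1 and 54.4, with 4 members measured). Class II genes reached the 100th percentile in all 5 (0.327, 0.25, 0.331, 0.0725 and 0.0857, the last over 6 members); in mouse and human breast they led a subcluster together with B-cell or macrophage genes. With cells thinned to 1000 UMIs the pancreatic libraries no longer passed for class II genes (percentiles 79.0 and 37.4), and 1 breast library passed for inflammatory genes (96.4, with 3 members). TGF-beta genes passed the 95th percentile in 1 library, human breast replicate 1, at 97.3; after thinning they passed in both pancreatic libraries instead (99.6 and 95.4). Without thinning, matrix proteases and inhibitors were below the 95th percentile in human breast replicate 1 (91.0) and in both pancreatic libraries (69.4 and 56.1). Basement membrane genes were below it, likewise without thinning, in human breast replicate 2 (89.6). Over 14 lists and 5 libraries 52 of 70 values passed the 95th percentile.

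**Figure D5:**
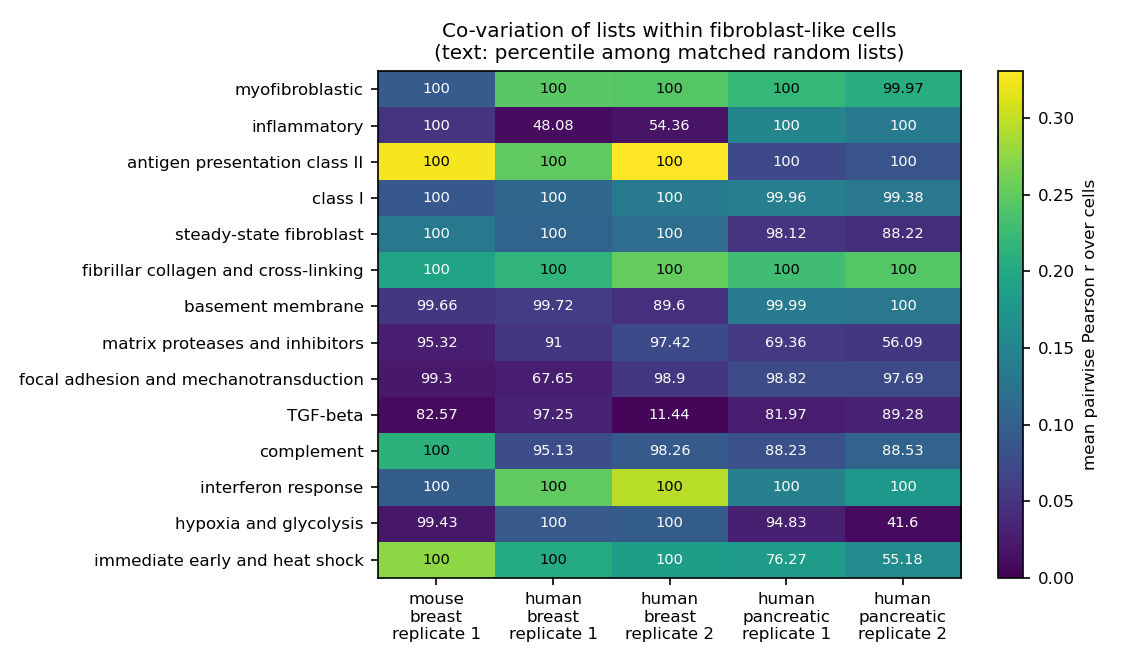
Mean pairwise Pearson correlation over fibroblast-like cells (color) for 14 lists in 5 libraries; the text in each field is the percentile among matched random lists. Fibrillar collagen genes stood at 100 in every library, and inflammatory genes at 48.1 and 54.4 in the human breast libraries.

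Subclusters of fibroblast-like cells matched across groups in part. There were 7 in mouse, 6 in human breast and 6 in pancreas, and of 20 best matches 9 were reciprocal, with a mean r of 0.232. A mouse subcluster of 90 cells led by TNC, LRRC15 and TAGLN matched a pancreatic one of 181 cells led by ACTA2, TAGLN and COL11A1 (r = 0.286). A mouse subcluster of 161 cells led by POSTN and ELN matched a pancreatic one of 472 cells led by SFRP2 and CTHRC1 (r = 0.253). Mouse cells led by APOE, CXCL12 and C3 (267) matched breast cells led by GSN, CFD and C3 (194; r = 0.267) and pancreatic cells led by C7 (189; r = 0.178). The largest mouse subcluster, 355 cells led by the adventitial genes PI16, CLEC3B and CD34, had no reciprocal match in either human tissue. In pancreas, an unnamed cluster of 56 cells with MFAP5, CLEC3B and TNXB among its leading genes was not among the cells subclustered. A pancreatic counterpart is therefore not excluded. The mouse subcluster of 90 cells also matched 12 breast cells with cycling genes such as CENPF and TOP2A (r = 0.198), and breast cells led by COL11A1 (194) matched pancreatic cells led by FOSB and SFRP2 (275; r = 0.305). Mouse cells led by T-cell genes (22) matched breast cells led by T-cell genes (35; r = 0.274) and pancreatic cells with HAS1 and CCL2 (95; r = 0.161). The mouse subcluster of 161 cells also matched breast cells led by POSTN (273; r = 0.166).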

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

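The test of interaction was fixed before the data were examined, and the tests of explanations were chosen after their patterns had been seen; the last test of class II genes and the tests with hashtags assigned by a 2-fold margin or taken class by class were written after the results of those before them.

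The effect of tissue differed between fibroblast-like and macrophage-like cells in 1613 genes, a difference between cell classes tested as an interaction. The 10 genes listed with opposite calls had interaction log2 values of -9.90 (F13A1), 6.45 (OLFML3), 6.43 (C3), 5.68 (NFATC2), -5.19 (TMEM158), 4.71 (KHDRBS3), 4.70 (MMP2), 4.69 (CLDN1), -4.69 (PTPRE) and 4.65 (PTGS2). No explanation of these differences was tested; the macrophage-like class held 6 clusters in breast and 1 in pancreas.

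The hashtag counts, which the comparisons between libraries do not use, differed between the groups of libraries. Hashtag 8 made up at least 96.3% of the hashtag UMIs of each pancreatic library. Hashtags 8, 9 and 10 made up at least 99.99% of those of each human breast library, and hashtags 4, 5 and 6 99.8% of those of the mouse library. The breast libraries carried the 3 tags at 43.0%, 9.90% and 47.1% in replicate 1 and at 44.5%, 9.05% and 46.5% in replicate 2.

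More immediate early and heat shock genes rose than fell in pancreatic tumors in each of the 4 classes, a pattern that handling of the tissue could give. Were 1 group of breast cells with low levels behind it, some hashtag group would lie near the pancreatic level, but the lowest median log2 ratio over the 3 hashtags and 4 classes was 0.597 with the mixture model and 0.479 with the 2-fold margin, both in macrophage-like cells. The latter lies under the limit of 0.5 set for the test. Over both assignments the lowest median was 0.654 in fibroblast-like, 1.06 in mural-like and 0.865 in T/NK-like cells. In T/NK-like cells the lower quartile of members also reached the limit in every group, which argues against such a group there, and in the other classes it stays open. The prediction for depth was that thinning would end most calls, but 95.7% of the risen members (45 of 47) still rose. The calls thus did not rest on the unequal totals of the sums. Thinning of sums leaves the expected share of each gene unchanged, so it could not exclude an effect of depth per cell. More members rose than fell in 4 of 4 classes, but this is the pattern itself and no test of handling. With 1 pancreatic hashtag, handling and tissue cannot be told apart here.

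More interferon-response genes fell than rose in pancreatic tumors in each of the 4 classes, with 5 of 11 called in mural-like cells and BST2 risen in fibroblast-like cells. The lowest median log2 ratio of a breast hashtag group over pancreas was 0.543 with the mixture model, in mural-like cells with 8 of 11 members above 0. With the 2-fold margin it was -0.425, in the 17 fibroblast-like cells of hashtag 9. In fibroblast-like cells hashtags 8 and 10 both lay above pancreas, with medians of 1.84 and 2.85 by mixture and 1.65 and 2.70 by margin. Their lower quartiles were at least 1.30. These values argue against 1 high group alone as the source in fibroblast-like cells, although hashtag 9 may be low. In mural-like cells 1 group of breast cells with high levels could still be the source. In macrophage-like and T/NK-like cells the lowest medians by either assignment were 1.58 and 2.59, with lower quartiles of at least 1.05 and 2.15, which argues against it there. Without the breast cluster of 184 cells led by CXCL11 and IFIT2 the median ratio in macrophage-like cells was 1.58, against 1.71 with it, so that cluster is unlikely to be the cause there. After thinning, 34 of 37 fallen members (91.9%) still fell, which again does not exclude an effect of depth per cell. Whether a donor, an earlier treatment or the tissue sets the level stays open, since 1 pancreatic hashtag gives no other sample.

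Class II genes varied together within fibroblast-like cells, which could reflect antigen-presenting fibroblasts or immune cells in the same droplet. When cells with 2 or more UMIs of immune markers, immunoglobulins left out, were removed, the mean correlation fell by more than a factor of 2 in 4 of 5 libraries. It fell from 0.327 to 0.0874 in mouse, from 0.25 to 0.0365 and 0.331 to 0.0683 in human breast, and from 0.0984 (8 members here) to 0.0337 in pancreatic replicate 2, but only from 0.0725 to 0.0687 in pancreatic replicate 1. With immunoglobulins among the markers it did so in 3 of 5 libraries, but that test removed 92.1% of the mouse cells and says nothing there about immune cells in the same droplet. Removing as many cells at random left the correlation in mouse and human breast at 0.111 or more in every one of 100 draws. In pancreatic replicate 2 the draws had a median of 0.0972 and a lowest value of 0.0312, so 0.0337 lay near the lowest draws but not below all of them. How many draws reached 0.0337 or less was not counted. Only the mouse and human breast libraries, 3 in all, fell below every draw. A fibroblast that expresses immune markers of its own would be removed too, so the removal alone leaves both explanations open. In mouse, class II genes peaked in a subcluster of 102 cells also led by the B-cell genes CD79A and IGHM (centred mean 1.0, next highest -0.1). In human breast they peaked in 8 cells also led by the macrophage genes C1QC and C1QA (1.393, next highest -0.157). These values argue against antigen-presenting fibroblasts alone in mouse and human breast. In pancreas both explanations stay open.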

How the results depend on the processing

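The tests named after hashtags, thinning and marker scoring were chosen only after the results were seen; the other alternatives were fixed before the data were examined. Of 4971 alternatives of the 247 called results for genes selected by the rule, 4702 kept call and direction, 268 lost the call and 1 reversed. MFAP5 in fibroblast-like cells rose by 0.34 without removal of doublets (adjusted p = 0.00517; -0.54 with it), and the cause was not tested. The losses fell mostly on the hashtag splits (54 with the mixture model, 69 with the 2-fold margin), on DESeq2 (25) and on leaving out breast replicate 2 (21); DESeq2 size factors and a stricter low-count filter ended no call.

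The number of genes called in fibroblast-like cells, 3912, was 2396 by DESeq2, 2424 to 2775 without 1 library, 1815 after thinning, and 437 and 416 with the hashtag splits. The 453 in mural-like cells were 205 by DESeq2, 272 (without breast replicate 2) to 427 without 1 library, 230 after thinning, and 106 and 201 with the hashtag splits. The 2725 in macrophage-like cells were 1243 by DESeq2, 924 with equal cells per library, 1822 to 2182 without 1 library, and 2065 and 1545 with the splits. The 1640 in T/NK-like cells were 569 by DESeq2, 997 (without breast replicate 2) to 1322 without 1 library, 979 with at least 1000 UMIs per cell, and 903 and 798 with the splits. Fewer libraries, cells, counts or genes go into most of these sums, but not for DESeq2, where the cause was not tested. Some signs also changed: with at least 1000 UMIs per cell those of 67 of 1390 T/NK-like calls tested again, 2 of them called in the other direction, and with equal cells those of 29 of 2015 macrophage-like calls, 0 of them called. The other alternatives changed at most 9 signs each, with at most 2 called, and no cause was tested. The number of interaction genes, 1613, was 575 with equal cells and 1526 with size factors. Of 32 lists camera called 11, 0 with an estimated correlation, 11 or 12 without 1 library and 8 of 29 with the hashtag split. With 2 libraries per tissue an estimated correlation could hardly call any list, so that 0 is no evidence against the 11.

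Samples of the tissues share only a replicate number. A block on that number gave 3757, 515, 2686 and 1634 genes in the 4 classes in the order above and 14 lists; residual correlations of equal numbers were 0.0298, -0.0303, -0.00556 and -0.0271, so no pairing was assumed.

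The share difference of fibroblast-like cells, 36.2 points, ranged from 32.8 to 41.1, that of macrophage-like cells from -29.1 to -17.2, and that of T/NK-like cells from 6.75 to 23.3. The rank correlation between mouse and human breast, 0.451, was 0.473 with a minimum of 10 CPM, 0.470 with the other classes weighted equally and 0.398 without markers and variable genes. Between mouse and pancreas, 0.489, it was 0.521, 0.501 and 0.430, and 0.482 with a pseudocount of 10. Between human breast and pancreas, 0.445, it was 0.593 with equal weights, 0.430 with that pseudocount and 0.389 without markers and variable genes. The order of the 3 pairs thus depends on the weighting and choice of the other cells, since equal weights also left out unnamed cells. Co-variation passed in 51 to 55 of 70 fields. Reciprocal matches of subclusters, 9, were 16 at resolution 1.0, where there are more subclusters, and 8 to 10 otherwise. Comparisons of endothelial-like and epithelial-like cells and their alternatives were not run. Simulated 2-fold changes were recovered in 29.1% of genes in fibroblast-like cells.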

Other observations

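The tests of the keratin-high cluster were chosen only after the cluster had been seen. A pancreatic cluster of 103 cells with fibroblast markers, left unnamed and not part of any comparison, expressed keratins. KRT8 stood at 890 CPM in it and at 13.2 in fibroblast-like cells of the same libraries, and MSLN, which mesothelium and some carcinomas express, at 108 and 0.536 CPM. WT1, a factor of mesothelium, stood at 140 and 28.8 CPM, and COL1A1 at 6403 and 19300.0 CPM. Of 8 mesothelial genes 7 were highest in this cluster among the pancreatic clusters, CALB2 among them (52.6 CPM against 16.4 in the next), and of 8 genes chosen for ductal tumor cells 6 were highest in it. A UMI of a mesothelial gene was found in 48 of its cells (46.6%), of a ductal gene other than MUC1 in 10 (9.71%) and of both in 2. With MUC1 counted, 34 (33.0%) held a ductal gene and 16 both kinds. Among 1242 fibroblast-like cells of like depth (median 11907.5 UMIs against 11779) the shares were 3.54% for mesothelial genes, 1.21% for ductal genes without MUC1 and 10.7% with it. The labels name no such cells, and whether the cluster holds 2 kinds of cells was not tested further.

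The mouse tumors were rich in lymphoid cells: B-like cells were 28.5%, T/NK-like cells 21.3% and plasma-like cells 15.5% of the library, and neutrophil-like cells 3.19%. A further cluster of 5.69% held B-cell and T-cell genes together and was left unnamed. In human breast tumors the shares moved with the hashtag: macrophage-like cells were 20.4% and 45.7% of the cells that the mixture model assigned to hashtags 8 and 10, and fibroblast-like cells 14.0% and 4.39%. Hashtag 9 is left out, since only 43.6% of its cells that were also assigned by the 2-fold margin got the same tag.

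Resampling the cells of a class across the 2 libraries of a tissue gave a difference between libraries as large as the observed one in 6 of 100 draws for breast fibroblast-like cells, 72 for pancreatic ones. It did so in 0 of 100 draws for breast macrophage-like cells and 89 for pancreatic ones, in 4 of 100 for T/NK-like cells of either tissue, and in 45 and 48 for mural-like cells of breast and pancreas. With 1 library against 1 this does not tell whether the libraries are captures of 1 pool. For mural-like cells of both tissues and for pancreatic fibroblast-like and macrophage-like cells, the libraries differed no more than random sets of cells commonly did. The libraries of these groups thus brought little spread beyond that of drawing cells into the p values.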
